A study of Mus musculus with 8 samples.

How the data were processed

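Bilateral amygdala punches of 1 mm from 8 adult male mice, 4 per group, were profiled on a miRNA array with probes for human, mouse and rat. Per the labels' protocols, 500 ng of total RNA from each animal was labelled with Hy3 and a pool of equal amounts from the individual animals with Hy5, and a company carried out the labelling, hybridisation and data analysis. Per the file headers, the deposited scanner files give spot intensity and local background intensity for 1 channel, with a flag per spot. This channel was taken as the sample's Hy3 channel, because it lights the Hy3 landmark spots and its deviations correlate positively with the deposited ratios, between 0.315 and 0.650 by array over 188 bright probes. The Hy5 intensities were not used here.

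The authors also deposited a table of log ratios of sample to pool, taken here as log2. Its log base, background correction and normalization are not given in the sources used here. The slope of the log2 Hy3 signal on the ratio over 20 probes with wide ranges was 0.966, near what log2 gives. The direction, sample over pool, was taken from the positive correlations and the dyes in the labels. The correlations give it only if the channel is Hy3, for which the landmark spots are the separate evidence. A Hy5 channel with a ratio of pool to sample would correlate positively too. The column medians were 0.0021, 0.018, 0.015 and 0.010 on the home cage arrays and 0.026, 0.016, 0.025 and 0.025 on the fear conditioned arrays, so the ratios are centred near 0. Between 13 and 25 values per array are missing. Every column of this table was matched to a sample.

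The design fixed before the data were examined was a within-array loess fit of the log ratio, with a stated fallback for files of a single colour. With 1 channel in the scanner files, the fallback was used: normexp background correction with offset 50 on the mean spot signal and median background, then quantile normalization between arrays over the capture probe spots, in limma 3.58.1 under R 4.3.3. Control spots were left out after normexp, as were spots flagged 3 (poor shape) and 4 (background above signal). The spots of a probe, 4 for 2601 of the 2607 probes, were averaged on the log2 scale. Because of the offset, log2 differences of dim probes understate the change.

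Probes with a mouse name were tested if detected on at least 4 of 8 arrays, where detected means above the 95th percentile of empty and negative control spots. All 1034 met this, so the filter removed none. Against the negative control probes alone, 624 probes were above the 95th percentile on 4 or more arrays, 485 on all 8 and 259 on none, and differences of probes below it are not read as changes. Probe names are those of the array's design, in which an asterisk marks the less abundant arm, and 18 mouse probes carry several names. Probes without a name (1487), viral probes (57) and other small RNA probes (29) were kept out of the comparison.

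Groups were compared with limma's lmFit and eBayes (two-sided, Benjamini-Hochberg adjusted p under 0.05), miR-34a also with an exact permutation test over 70 arrangements, and 16 lists with camera at a preset correlation of 0.01, with the estimated correlation and fry beside it. By fry, 0 lists passed for a shared direction or for change in either direction. Lists needed at least 3 probes. Named miRNAs were those that passed (the 12 largest changes each way if more), the 8 higher and 8 lower probes with the smallest unadjusted p among those whose groups did not overlap, every probe of miR-34a, miR-132, miR-212, miR-134, miR-124, miR-182, miR-183 and miR-96, and in each list the member with the smallest p in each direction.

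On data simulated from the Hy3 means and SDs of 1003 probes, with 200 changed in each of 20 runs, the fit recovered 78.6% of log2 changes of 0.25, 94.3% of 0.5 and 98.7% of 1, and 4.64% of calls were false. For the ratios of 995 probes the shares were 58.7%, 92.1% and 98.4%. The simulated values of probes were independent, which real arrays are not. The shares hold for 200 changed probes. Where fewer change, the adjusted threshold is stricter, so a lower share of changes of the same size would pass. Alternatives changed the offset (10), background subtraction, scaling, filter, probe set, spot summary, array weights, source of values and arrays. Each array was on its own slide, no scan date was found in the files used here, and the slides of the groups carry separate runs of numbers, so slide order and group cannot be told apart. Figures were drawn with matplotlib 3.10.9.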

Results

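MicroRNAs were measured in the amygdala, the temporal lobe structure needed for learned fear, of adult male C57/Bl6J mice. Tissue came from 4 mice left in the home cage and from 4 mice killed 30 min after auditory fear conditioning with 5 pairings of a 6 kHz tone and a 0.6 mA foot shock, each mouse on its own array. Each sample's RNA carried the green dye Hy3 and was hybridised together with a Hy5-labelled pool of RNA from all the animals to probes made of locked nucleic acid, a base analogue that binds short RNAs tightly. Each array held 12312 spots, of which 10488 belonged to miRNA and other capture probes, and 1034 probes carried a mouse miRNA name. Between 569 and 659 of these exceeded the 95th percentile of the negative control probes on an array. The number of arrays limits the precision of every value. Values are given as the normalised Hy3 signal (log2, mean ± SD, n = 4 per group) and beside it as the log ratio of sample to pool that the authors deposited.

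The comparison asked which miRNAs differ in the amygdala soon after cued fear learning, when the memory is being consolidated. The home cage mice received no tone and shock pairings. Learning therefore cannot be told apart from exposure to the tone, the shock or any other part of the conditioning procedure. In the Hy3 signal, 2 of 1034 mouse miRNA probes passed the limma test at an adjusted p under 0.05, and neither passed in the ratio to the pool. mmu-miR-1900 fell from 7.71 ± 0.055 to 7.41 ± 0.040, a difference of -0.30 (SE 0.034, adjusted p = 0.0276), and was lower on all 4 conditioned arrays than on any home cage array. Its deposited ratio went the other way, by 0.18 (SE 0.088). mmu-miR-883b-5p rose from 6.60 ± 0.041 to 6.86 ± 0.058, a difference of 0.26 (SE 0.035, adjusted p = 0.0449), and was higher on all 4 conditioned arrays, while its ratio differed by 0.14 (SE 0.065). In the deposited ratios 0 of 1033 probes passed in limma, with 79 at an unadjusted p under 0.05 and a lowest adjusted p of 0.418. Without home cage array 1 the ratios also gave 0, with 6 probes at an adjusted p under 0.10 and a lowest of 0.0918, and without any other single array they gave 0 at either level. Leaving out single arrays gave 1 call (miR-1900) without home cage array 3, 1 (miR-883b-5p) without fear conditioned array 2, 2 (miR-1900 and miR-150) without fear conditioned array 4, and 0 without any of the others. With an offset of 10 both passed, miR-883b-5p at 0.43 and miR-1900 at -0.38. Neither passed without background subtraction (0.35 and -0.20), with median centring (0.30 and -0.098) or with spike-in centring (0.075 and -0.33). Only miR-1900 passed among probes above the negative controls on at least 4 arrays, and only miR-1900 with flagged spots kept. miR-883b-5p was dim, with probes for viral miRNAs at a median of 6.38 in the same signal.

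**Figure D1:**
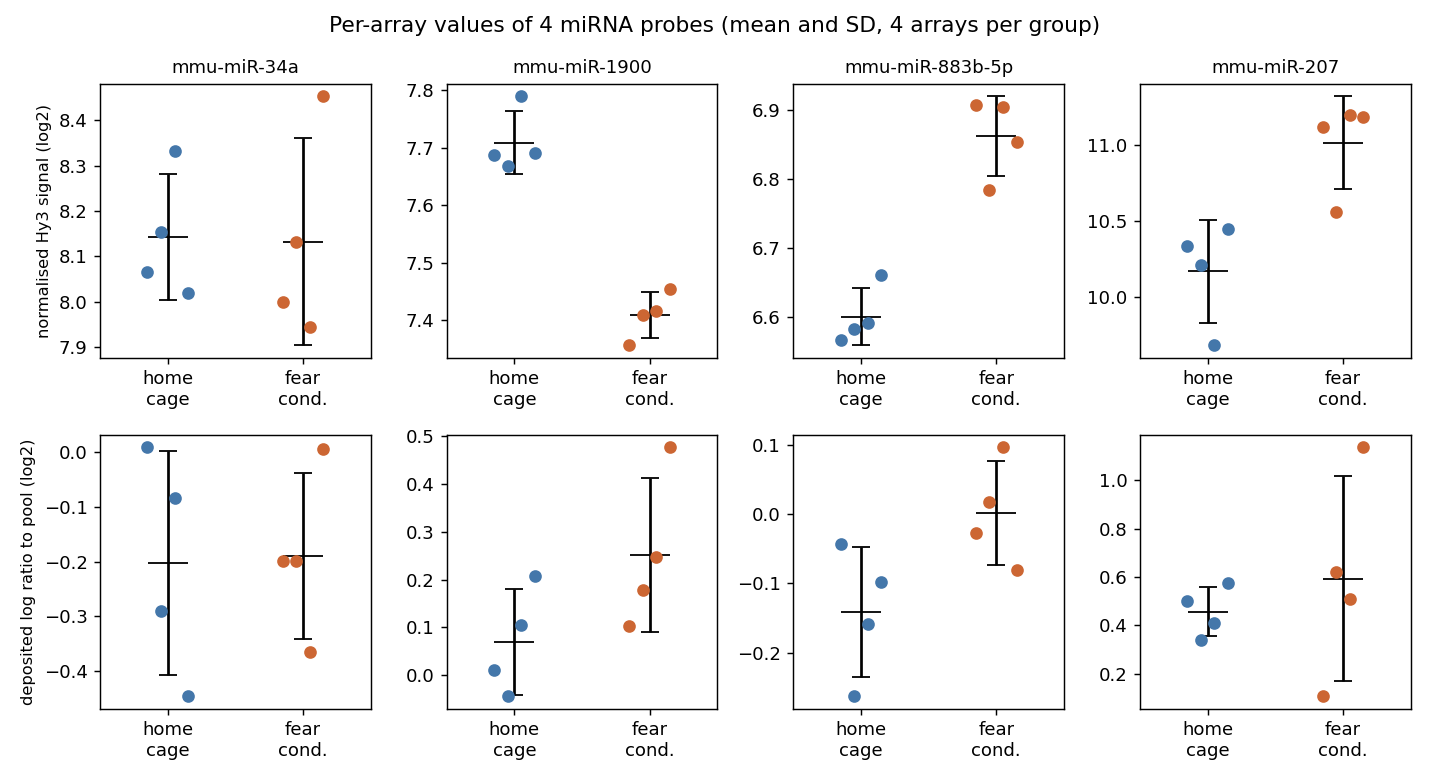
Normalised Hy3 signal (upper panels, log2) and deposited log ratio to the pool (lower panels, log2) of 4 probes on the 4 home cage (blue) and 4 fear conditioned (orange) arrays, with mean and SD. miR-1900 is lower after conditioning in Hy3 by 0.30 log2 units but higher in the ratio by 0.18, and miR-34a overlaps between groups in both.

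At an unadjusted p under 0.05 the Hy3 signal gave 146 probes, 52 higher and 94 lower after conditioning, where chance gives 51.7. Such p-values were not limited to mouse probes. In a separate limma fit, 12 of 57 viral, 5 of 29 other small RNA and 230 of 1485 unnamed probes reached them. Among mouse probes the count was 69 with median centring, of which 26 were higher, and 3 with spike-in centring. The Hy3 count was 93 without home cage array 3, 96 without fear conditioned array 1 and 96 without fear conditioned array 3, of which 30, 42 and 29 were higher. The ratios gave 79 such probes, 65 higher and 14 lower, and with each array's ratios median centred 68, of which 41 were higher. The ratio count was 130 without home cage array 1 and 49 without home cage array 2, of which 91 and 39 were higher. The sets shared 10 probes, 8 of them with the same sign, against 11.2 for independent sets. In Hy3, the values of the groups did not overlap for 41 probes higher and 54 lower after conditioning, 9.47% of the 1003 probes with 8 values, where chance gives 2.86%. In the ratios they did not overlap for 54 of 995 probes, or 5.43%. Across probes, which are not independent replicates, the Hy3 and ratio differences correlated with Pearson's r = 0.18 and Spearman's rho = 0.21, although the ratio contains the Hy3 value.

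**Figure D2:**
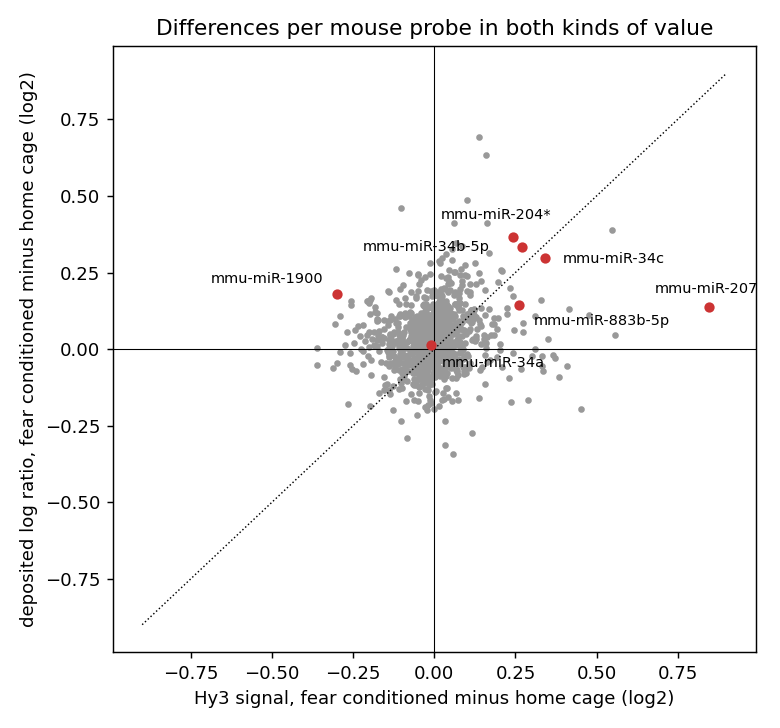
Difference between fear conditioned and home cage arrays for each mouse probe, in the Hy3 signal (x axis, log2) and in the deposited log ratio (y axis, log2). Each grey point is a probe, red points are named, and the dotted line marks equal differences. The correlation across probes is 0.18, and miR-207, at 0.85 in Hy3, is at 0.14 in the ratio.

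Among probes whose groups did not overlap in Hy3 and that did not pass, those with the smallest p that were lower after conditioning were miR-361* (-0.17, SE 0.026), miR-3072 (-0.14, SE 0.023), miR-92b (-0.18, SE 0.033), miR-150, a lymphocyte miRNA (-0.26, SE 0.050), miR-103 (-0.29, SE 0.059) and miR-615-3p (-0.22, SE 0.051). miR-449a* also ranked among these, ahead of miR-150, but lay below the negative controls on every array. In the ratio miR-361* and miR-3072 kept this direction (-0.14 and -0.15), whereas miR-92b, miR-150 and miR-103 were at 0.099, 0.16 and 0.11 and miR-615-3p at -0.0066. With median centring of Hy3 miR-361* was at -0.075, miR-3072 at -0.013, miR-92b at -0.061, miR-150 at -0.030, miR-103 at 0.058 and miR-615-3p at -0.14. Those higher were miR-883a-5p (0.35, SE 0.063), miR-1192 (0.27, SE 0.058), miR-493* (0.48, SE 0.111), miR-138-2* (0.27, SE 0.058), miR-138-1* (0.15, SE 0.035) and miR-1957 (0.15, SE 0.036), with miR-210* (0.17, SE 0.034) above the negative controls on 1 home cage and 4 fear conditioned arrays. Their ratio differences lay between -0.063 for miR-138-2* and 0.13 for miR-210*, and with median centring of Hy3 they ran from 0.14 for miR-210* to 0.63 for miR-493*. Under quantile normalization the adjusted p of all these lower and higher probes ran from 0.0704 for miR-361* to 0.152. Chosen after its values were seen, mmu-miR-207 had a Hy3 difference of 0.85 (SE 0.20, adjusted p = 0.152), and a ratio difference of 0.14 (SE 0.173).

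miR-34a, a p53-induced miRNA, is the one the study followed up on these same arrays, so its p is not independent evidence. It did not differ between the groups in either kind of value. The Hy3 signal was 8.14 ± 0.14 in the home cage and 8.13 ± 0.23 after conditioning, a difference of -0.011 (SE 0.118, adjusted p = 0.966, two-sided exact permutation p = 0.886). Its 95% interval ran from -0.28 to 0.26. The ratio was -0.20 ± 0.20 and -0.19 ± 0.15, a difference of 0.013 with an interval from -0.23 to 0.25 (exact permutation p = 0.971). The smallest p that the 70 arrangements of the arrays allow is 0.0286. The sign of this small difference turned with median centring, to 0.21, and in other settings, and it did not pass in any of them.

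Of the other members of the list of the miR-34 and miR-449 family, miR-34c was at 8.85 ± 1.10 and 9.19 ± 0.97 and miR-34b-5p at 9.19 ± 1.14 and 9.46 ± 1.00, named here after their values were seen. These are products of one primary transcript, and their SDs were several times that of miR-34a. miR-204, a miRNA abundant in the choroid plexus, was at 8.92 ± 0.93 and 9.47 ± 0.84 on the same arrays. Of the list's 10 probes 6 were higher and 4 lower, 0 passed over all probes, and adjusted over the list alone 1 passed. That probe was miR-449a*, which lay below the negative controls on every array, so its difference is not read as a change. The list holds the miRNA that the study chose on these arrays, so its count is not independent evidence.

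**Figure D3:**
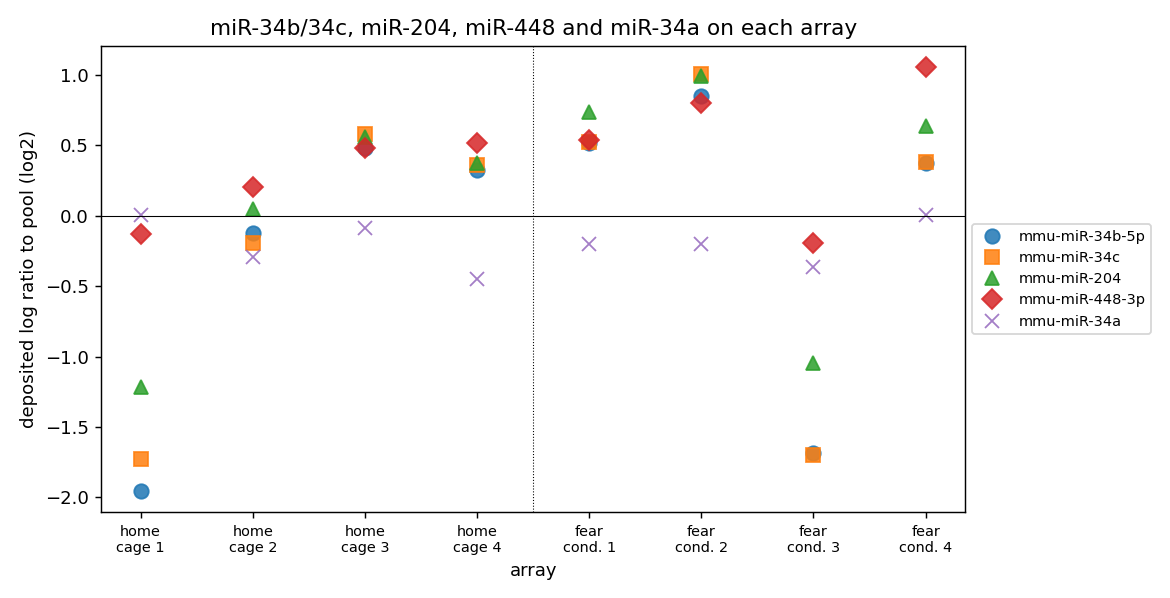
Deposited log ratio to the pool (y axis, log2) of 5 probes on each of the 8 arrays (x axis), home cage on the left and fear conditioned on the right of the dotted line. miR-34c is at -1.73 on home cage array 1 and at -1.70 on fear conditioned array 3, while miR-34a stays between -0.45 and 0.0086 on all arrays.

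The miRNAs known from neuronal activity and memory did not pass. miR-132, a CREB-induced miRNA, was at 9.29 ± 0.17 and 9.22 ± 0.17, a difference of -0.068 (SE 0.107), and miR-212-5p, from the same transcript, differed by -0.18 (SE 0.058, adjusted p = 0.301). miR-132* differed by -0.15 (SE 0.099) and miR-212-3p by -0.015 (SE 0.080). miR-124, the main neuronal miRNA, was at 14.46 ± 0.059 and 14.26 ± 0.16, a difference of -0.19 (SE 0.078, adjusted p = 0.344), with -0.084 in the ratio, and miR-124* differed by -0.0055. Over all settings tried the difference of miR-124 ran from -0.32 to -0.022, the latter with median centring. miR-134, which acts at dendritic spines, was above the negative controls on 7 of 8 arrays and differed by 0.065 (SE 0.047). Probes of miR-182, miR-182*, miR-96, miR-96*, miR-183 and miR-134* were below the negative controls on at least 4 of 8 arrays, so their differences are not read as changes, and miR-183* differed by -0.032 (SE 0.032). With 1 array left out, miR-132 ranged from -0.13 to 0.0017, miR-212-3p from -0.063 to 0.030 and miR-124* from -0.045 to 0.023, while mmu-miR-132* was at -0.086 without home cage array 1, mmu-miR-134 at 0.025 without fear conditioned array 3 and mmu-miR-183* at -0.0090 without fear conditioned array 4.

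None of 16 lists of related miRNAs passed the limma camera test, with a lowest adjusted p of 0.637, of 0.846 with an estimated correlation and of 0.659 in the ratios. In each list 0 members passed over all probes. Counts of higher and lower members include probes below the negative controls. Above these controls on all 8 arrays were 8 of 19 activity-induced, 15 of 36 memory and stress and 11 of 28 miR-17~92 probes. Relative to the median of all probes, the medians of the miR-29 family (0.020) and of the miR-34 and miR-449 family (0.064) kept their sign throughout. This held in every scaling of Hy3 tried, without background subtraction and in the ratios. All of these settings use the same 8 arrays, so a kept sign is not replication. Of the 10 probes of the miR-34 and miR-449 family, 5 were above the negative controls on all 8 arrays. Under quantile normalization the family's median fell between miR-449a (0.036) and miR-34a* (0.084). Both lay below the negative controls on at least 4 of 8 arrays, so the family's kept sign is not read as a change. The median of the miR-29 family relative to all probes was only 0.0061 in the ratios. Each of the other lists turned sign in at least 1 of these settings, such as the neuron-enriched list from -0.028 to 0.11 with median centring and the cluster from miR-379 to miR-410 from -0.021 to 0.062. The let-7/miR-98 family turned only without background subtraction, from 0.040 to -0.0012. The 38 neuron-enriched probes had 27 lower and 11 higher, with miR-129-1-3p at -0.36 and miR-138-2* at 0.27, and an adjusted p of 0.637. The cluster from miR-379 to miR-410, an imprinted group of brain miRNAs, had 47 of 71 lower, with miR-329 at -0.26 and miR-487b* at 0.090, and the same adjusted p. The activity-induced list had 12 of 19 lower, with miR-188-5p its highest-ranked higher member at 0.087 (adjusted p = 0.749 for the list). The memory and stress list had 21 of 36 lower, with miR-19b at 0.27 (adjusted p = 0.901), which is also the adjusted p of the miR-34 and miR-449 family. Without home cage array 1 miR-188-5p was at 0.054 and miR-19b at 0.13. The cluster of miR-183, miR-96 and miR-182 had 1 of 6 probes above the negative controls on all 8 arrays, so its signs are not counted (adjusted p = 0.749).

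Among the families, let-7/miR-98 had 12 of 20 higher, with miR-98 at 0.39 and let-7e* at -0.11 (adjusted p = 0.749). The miR-29 family had 4 of 7 higher, with miR-29b at 0.33 and miR-29a* at -0.21 (adjusted p = 0.727), the miR-30 family 8 of 11, with miR-30a at 0.24 and miR-30e* at -0.13 (adjusted p = 0.749), and the miR-17~92 clusters 15 of 28, with miR-20a at -0.12 (adjusted p = 0.637). miR-98, miR-29b and miR-30a were lower after conditioning in the ratio, by -0.093, -0.073 and -0.012. Without home cage array 1 miR-98 was at 0.21 and let-7e* at -0.073, and without fear conditioned array 4 miR-30a was at 0.13 and miR-30e* at -0.20.

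Lists of markers of cell types that a 1 mm punch can hold did not pass either. Oligodendrocyte markers had 7 of 11 lower, with miR-151-3p at -0.099, and their median of -0.045 and mean of 0.0033 differed in sign. Astrocyte markers had 11 of 14 lower, with miR-26a at -0.14 and miR-24 at 0.040, which ranged from -0.028 to 0.083 with 1 array left out. Microglia and leukocyte markers had 9 of 13 lower, and adjusted over the list alone 1 passed, miR-150, with no adjustment across the lists. miR-150 was at -0.030 with median centring of Hy3 and at 0.16 in the ratio. In the same list mmu-miR-467f was at 0.13, or 0.081 without home cage array 3 and 0.084 without fear conditioned array 3. The oligodendrocyte, astrocyte, and microglia and leukocyte lists had an adjusted p of 0.637 in camera, as did the ventricle and neighbouring region markers. In the latter list miR-204* was at 0.24 (ratio 0.36, adjusted p = 0.418 in limma). Of its 16 probes 11 were higher, but only 4 were above the negative controls on all 8 arrays, so these signs are not read as a shift. Vascular markers had 4 of 6 higher, with miR-145 at 0.16, or 0.068 without home cage array 1 (adjusted p = 0.727), and red blood cell markers 3 of 5 higher (adjusted p = 0.749), with a median of 0.022 and a mean of -0.0047.

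**Figure D4:**
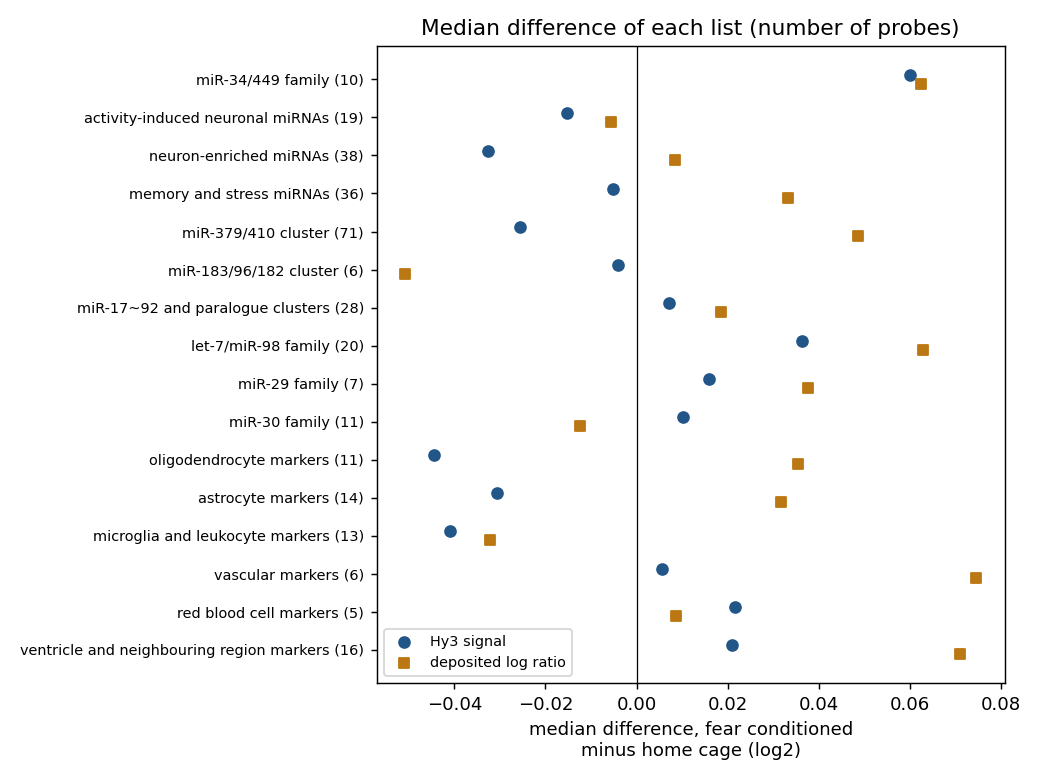
Median difference between fear conditioned and home cage arrays over the probes of each of 16 lists (x axis, log2), in the Hy3 signal (circles) and the deposited log ratio (squares), with the number of probes in brackets. All medians lie within 0.1 of 0, and none of the lists passed in either kind of value.

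The conditioned arrays were brighter before normalisation. The 95th percentile of the capture probe signal was 727 ± 146 against 543 ± 45.0 (exact permutation p = 0.0286, adjusted p = 0.0857 over 18 array measures compared). The spike-in probes, RNAs added in fixed amounts, were at 10.29 ± 0.097 against 9.98 ± 0.17 (exact permutation p = 0.0286, adjusted p = 0.0857). Home cage array 1 had 508 spots whose background exceeded the signal, against 0 to 10 on the other arrays, and a mean correlation with the other arrays of 0.977.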

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

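The comparisons of the Hy3 and ratio differences, and the counts of splits for probes at an unadjusted p under 0.05 and for lists, were tests chosen after the result was seen. The count of splits for the 2 calls and the background test of home cage array 1 were set out before.

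The first pattern is the difference in Hy3 that the ratio to the pool does not show. For the 2 calls chance cannot be excluded, since 2 of the 35 splits of the 8 arrays gave 2 or more and the highest other, which exchanges home cage array 4 with fear conditioned array 4, gave 6. For the 146 probes at an unadjusted p under 0.05, 1 of the 35 splits, the real one, gave as many, and the highest other, the same exchange, gave 130. This is the smallest share that the splits can give, and the count was chosen after it was seen, so chance is not excluded by it. Quantile normalization was the only scaling of Hy3 for which splits were counted. The count was 69 with median centring, 3 with spike-in centring, 93 without home cage array 3 and 96 without fear conditioned array 1 or 3. Of the viral probes, fitted apart, 12 of 57 also reached such a p in limma. In the ratios 4 splits gave 79 or more and the highest other gave 146, so chance cannot be excluded there, with a count of 130 without home cage array 1 and 49 without home cage array 2, and for the lists the splits say nothing, because with 0 passing all 35 must give as many (highest other 4). A candidate explanation of the Hy3 differences is an array difference that both dyes share, which a ratio on the same slide removes. Over the 146 probes the ratio difference was a median 0.211 of the Hy3 difference (bootstrap interval 0.104 to 0.309). The probes share the same 8 arrays and are not independent replicates, so this interval does not measure the spread between animals. Choosing probes by their Hy3 values also lowers this share by itself. miR-1900 went to 0.181 in the ratio against -0.30 in Hy3. For miR-883b-5p, at 0.143 in the ratio (SE 0.065) against 0.26 in Hy3, such an array difference cannot be told apart from a change in the tissue. Its ratio difference lies within its SE of 0.5 times the Hy3 difference. The authors' unstated normalization and an effect of conditioning stay open and untested.

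The second pattern is that home cage array 1 stood apart, with 508 spots of background above signal and a mean correlation with the other arrays of 0.977. Raised local background was tested as the whole cause by leaving out every probe with a spot at over 1.2 times the array's median background, which left 702 probes. The mean correlation with the other home cage arrays went from 0.979 to 0.990, while the lowest mean among the other home cage arrays was 0.997, so background accounts for part of the gap at most. A difference of the tissue punched stays open, and no biological explanation was tested.

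Dixon's criterion for a value far from the others of its group marked 13 of 122 groups of 4 values, among them the 508 spots and the correlation of 0.977 above, where chance marks 6.1. On home cage array 1 it also marked miR-449a at 6.36, miR-19b at 7.16, miR-98 at 9.01 and miR-29b at 13.10. Home cage array 2 had miR-200a* at 6.46, and home cage array 4 had miR-329 at 8.39 and 1397 spots of poor shape. Fear conditioned array 3 had miR-34a* at 6.55, and fear conditioned array 4 had miR-150 at 7.68, miR-23a* at 6.39 and miR-145 at 7.31. Outside the mouse miRNA probes, 12 of 1485 unnamed probes passed at an adjusted p under 0.05 in limma, adjusted without the mouse probes, whereas 5 of 2519 mouse and unnamed probes tested together passed, 2 of them mouse probes; the names of the unnamed ones are not given in the sources used here.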

How the results depend on the processing

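The alternatives chosen after seeing the data were cyclic loess, spike-in centring, the filter on negative controls, the kept spots, the median pixel signal, the ratios median centred or without single arrays, the estimated correlation with spike-in or median centring, and the fit without home cage array 1 and fear conditioned array 3. Against 2 calls, limma called 0 without background subtraction, 0 with median centring, 0 in the deposited ratios as they are, median centred or without any single array, 0 with spike-in centring, 0 without home cage array 1 and fear conditioned array 3, 1 above the negative controls, 1 with spots of poor shape or high background kept, 3 with cyclic loess or at an adjusted p under 0.10, 4 with the median over a probe's spots, 5 with unnamed probes added and 9 with array weights. At an unadjusted p under 0.05 it counted 146, against 135 without background subtraction, 69 with median centring, 3 with spike-in centring, 79 in the ratios, 68 in the median-centred ratios, 130 in the ratios without home cage array 1, 49 in those without home cage array 2 and between 93 and 175 with 1 array left out. Of those, 52 of 146 were higher, against 63 of 135 without background subtraction, 73 of 158 with cyclic loess, 65 of 79 in the ratios and 41 of 68 in the median-centred ratios. With median centring of Hy3 26 of 69 were higher, with spike-in centring 3 of 3, and with flagged spots kept 25 of 129. Calls stayed at 2 with an offset of 10, with quantile normalization over mouse probes, with detection on all 8 arrays and with the median pixel signal. Testing without a filter says nothing, since the filter removed no probe. Leaving out 1 array at a time gave 0 to 2 calls, with 1 without home cage replicate 3, 1 without fear conditioned replicate 2 and 2 (miR-150 and miR-1900) without fear conditioned replicate 4. No list passed in any setting except spike-in centring at the preset correlation, where 3 did. That pass says nothing about the lists: spike-in centring differs from median centring, where 0 passed (lowest adjusted p 0.202), by the same shift of -0.23 for each of the 1003 probes with 8 values, and with an estimated correlation 0 passed under it (lowest adjusted p 0.992). What changed the counts of calls was not tested. Loess was not run, because the scanner files used here hold 1 channel, so median centring was run on Hy3 and on the deposited ratios. A batch block was not run, because each array had its own slide and no scan date was found. Signal over background limits the dim probes, 259 of which were above the negative controls on no array.

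Same-numbered samples of the groups deviated with correlations of -0.073, -0.026, -0.53 and -0.0034, and no sample correlated best with its own number. The labels say nothing that ties equal numbers, so samples were treated as unpaired. These correlations cannot exclude a pairing by processing. With the replicate block 0 probes and 0 lists passed in limma, with 85 probes at an unadjusted p under 0.05.

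miR-34a changed sign in 9 settings and passed in none. Over the other 55 named miRNAs, 1290 values kept their sign and side of the threshold, 28 of the called ones no longer passed, 9 newly passed and 140 turned sign. The 1290 include settings that leave the log2 difference itself unchanged, where no sign could turn. Such settings were testing without a filter, with detection on all 8 arrays and with unnamed probes added. The values that turned, mostly of small differences, follow, and the cause was not tested. Those of miR-34a*, miR-449a, miR-449a*, miR-96, miR-96*, miR-134*, miR-143*, miR-144*, miR-182, miR-183 and miR-23a*, below the negative controls on at least 4 of 8 arrays, give the sign only and are not read as changes. With an offset of 10, the values were mmu-miR-124* 0.0096. Without background subtraction, the values were mmu-miR-212-3p 0.026, miR-34a 0.043, mmu-miR-188-5p -0.083 and mmu-miR-144* -0.16. With median centring of Hy3, the values were mmu-miR-103 0.058, mmu-miR-96* -0.0041, mmu-miR-183 -0.047, mmu-miR-132 0.27, mmu-miR-132* 0.12, mmu-miR-212-3p 0.22, mmu-miR-183* 0.043, mmu-miR-124* 0.10, miR-34a 0.21, mmu-miR-449a -0.023, mmu-miR-20a 0.065 and mmu-miR-29a* 0.028. With median centring of Hy3, further values were mmu-miR-30e* 0.10 and mmu-miR-26a 0.19. With quantile normalization over mouse probes only, the values were mmu-miR-96* -0.0033, mmu-miR-183 -0.0097 and miR-34a 0.0055. With the median over a probe's spots, the values were mmu-miR-182 -0.020 and mmu-miR-144* -0.010. With the replicate block, the values were mmu-miR-96* -0.0088. With array weights, the values were mmu-miR-134* 0.0043. In the deposited ratios, the values were mmu-miR-1900 0.18, mmu-miR-138-2* -0.063, mmu-miR-92b 0.10, mmu-miR-449a* 0.036, mmu-miR-150 0.16, mmu-miR-103 0.11, mmu-miR-96* -0.14, mmu-miR-134* 0.081, mmu-miR-132 0.080, mmu-miR-182 -0.066, mmu-miR-212-5p 0.029 and mmu-miR-124* 0.073. In the deposited ratios, further values were mmu-miR-96 0.043, miR-34a 0.013, mmu-miR-188-5p -0.0033, mmu-miR-329 0.14, mmu-miR-98 -0.093, mmu-let-7e* 0.0066, mmu-miR-29b -0.073, mmu-miR-29a* 0.047, mmu-miR-30a -0.012, mmu-miR-151-3p 0.032 and mmu-miR-143* 0.17. With cyclic loess, the values were mmu-miR-124* 0.011. With spike-in centring, the values were mmu-miR-210* -0.090, mmu-miR-1957 -0.077, mmu-miR-96* -0.21, mmu-miR-183 -0.28, mmu-miR-132 0.041, mmu-miR-34a* -0.19, mmu-miR-182 -0.19, mmu-miR-134 -0.17, mmu-miR-449a -0.25, mmu-miR-188-5p -0.11, mmu-miR-487b* -0.15 and mmu-miR-23a* -0.23. With spike-in centring, further values were mmu-miR-144* -0.21. With spots of poor shape and high background kept, the values were mmu-miR-183 -0.0064, mmu-miR-212-3p 0.024, mmu-miR-124* 0.017, mmu-miR-188-5p -0.22, mmu-miR-20a 0.0043 and mmu-miR-143* 0.093. With the median pixel signal, the values were mmu-miR-183 -0.0051, mmu-miR-96 0.0012 and mmu-miR-143* 0.00085. In the median-centred deposited ratios, the values were mmu-miR-1900 0.16, mmu-miR-138-2* -0.081, mmu-miR-92b 0.082, mmu-miR-449a* 0.019, mmu-miR-150 0.14, mmu-miR-103 0.090, mmu-miR-96* -0.16, mmu-miR-134* 0.064, mmu-miR-132 0.063, mmu-miR-182 -0.083, mmu-miR-212-5p 0.011 and mmu-miR-124* 0.056. In the median-centred deposited ratios, further values were mmu-miR-96 0.026, mmu-miR-188-5p -0.020, mmu-miR-329 0.13, mmu-miR-98 -0.11, mmu-miR-29b -0.090, mmu-miR-29a* 0.029, mmu-miR-30a -0.030, mmu-miR-151-3p 0.015, mmu-miR-143* 0.16 and mmu-miR-144* -0.0085. In the deposited ratios without home cage array 1, the values were mmu-miR-1900 0.16, mmu-miR-138-2* -0.058, mmu-miR-92b 0.078, mmu-miR-449a* 0.029, mmu-miR-150 0.15, mmu-miR-103 0.10, mmu-miR-615-3p 0.042, mmu-miR-96* -0.16, mmu-miR-134* 0.13, mmu-miR-132 0.085, mmu-miR-182 -0.041 and mmu-miR-212-3p 0.054. In the deposited ratios without home cage array 1, further values were mmu-miR-212-5p 0.078, mmu-miR-124* 0.079, mmu-miR-96 0.0038, miR-34a 0.083, mmu-miR-188-5p -0.019, mmu-miR-329 0.17, mmu-miR-98 -0.071, mmu-let-7e* 0.035, mmu-miR-29b -0.056, mmu-miR-29a* 0.069, mmu-miR-151-3p 0.024 and mmu-miR-143* 0.17. Without home cage array 1 and fear conditioned array 3, the values were mmu-miR-182 -0.045, mmu-miR-212-3p 0.010 and miR-34a 0.026. Leaving out 1 array at a time, these ranges spanned 0: mmu-miR-134* -0.018 to 0.0075, mmu-miR-212-3p -0.063 to 0.030, mmu-miR-144* -0.0010 to 0.036, mmu-miR-96* -0.044 to 0.085, mmu-miR-124* -0.045 to 0.023, mmu-miR-183 -0.019 to 0.019, mmu-miR-96 -0.024 to 0.0014, miR-34a -0.12 to 0.053, mmu-miR-143* -0.017 to 0.0044, mmu-miR-132 -0.13 to 0.0017, mmu-miR-182 -0.053 to 0.14 and mmu-miR-24 -0.028 to 0.083.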

Other observations

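miR-34b-5p and miR-34c, which come from the same primary transcript and are known from ciliated cells, varied more between arrays of a group than between the group means. Each mouse was on its own array, so animal, punch and array cannot be told apart. The deposited ratio of miR-34c was -1.73, -0.19, 0.58 and 0.36 on home cage arrays 1 to 4 and 0.53, 1.01, -1.70 and 0.38 on fear conditioned arrays 1 to 4. miR-34b-5p was at -1.96, -0.12, 0.48 and 0.33 and at 0.52, 0.85, -1.69 and 0.38. miR-204, abundant in the choroid plexus, was at -1.22, 0.045, 0.56 and 0.38 and at 0.74, 0.99, -1.04 and 0.64, and miR-448-3p, from an intron of the serotonin 2C receptor gene, at -0.13, 0.20, 0.48 and 0.52 and at 0.54, 0.80, -0.20 and 1.06. miR-200b, of the same list as miR-204, was at 0.033, 0.12, 0.21 and 0.25 and at 0.19, 0.17, 0.24 and 0.44, and miR-34a at 0.0086, -0.29, -0.083 and -0.45 and at -0.20, -0.20, -0.36 and 0.0048. The values of miR-34c fall into separate clusters, so no correlation over the 8 arrays is given. Tests of an array difference shared by both dyes and of choroid plexus tissue were run and withdrawn. They compared arrays chosen by their own miR-34c values, so no conclusion is drawn from them.

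miR-204* had the smallest unadjusted p of all probes in the ratios. Its ratio was -0.16 ± 0.064 in the home cage and 0.21 ± 0.13 after conditioning, a difference of 0.36 (SE 0.071, adjusted p = 0.418 in limma). In Hy3 it differed by 0.24, with no overlap between the groups in either kind of value. On fear conditioned array 3 it was at 0.39, where miR-204 was at -1.04.

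Probes for viral miRNAs give a level of signal for sequences foreign to the mouse. Their 95th percentile lay between 87.7 and 147 on the arrays, and 220 to 223 mouse probes exceeded it on home cage arrays and 233 to 244 on fear conditioned arrays (exact permutation p = 0.0286, adjusted p = 0.0857 over 18 array measures compared), against 569 to 659 that exceeded the negative control probes.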
